A study of Homo sapiens with 12 samples.

How the data were processed

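RNA-seq libraries of 143B cells, an established human osteosarcoma cell line, were compared in 4 groups of 3 libraries, which the sample titles name NC (the control), BSG, M-BSG and M-BSG-Hot. The labels do not spell out these names. The series title speaks of a borosilicate bioactive glass and of magnetic hyperthermia, and M-BSG and M-BSG-Hot carry the same material name in the sample titles, the latter with a plus sign. One identical treatment text, which names the magnetic system and an alternating magnetic field, stands on all 12 samples including the controls, so the labels do not say for each group which material, field, dose or exposure time was applied. Cells were grown in DMEM with fetal bovine serum, RNA was extracted with an RNeasy Mini Plus kit, and libraries were built from total RNA with a SMARTER mRNA-Seq kit, per the labels' protocols. Nothing in the labels says that the 3 samples of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

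For each sample the authors deposited a table of counts per gene symbol and a table of FPKM. The deposited counts are whole, unnormalised numbers for 24180 symbols in each of the 12 libraries. The deposited FPKM values are the same counts rescaled, as the values themselves show: 100% of the values above 0 match the count divided by a gene length and by the summed counts of the library, within a relative tolerance of 1e-06, and 100% of these gene lengths are whole numbers. The aligner, the counting program, the annotation and whether counting used strand are not given in the sources used here. The submitters' processing notes list GRCm38 and mm10, both names of a mouse assembly, while the tables hold human gene symbols, so the build behind the counts is unresolved and no coordinates are given. The tables carry symbols and no other identifier. Symbols were matched to an NCBI RefSeq gene table of human assembly GRCh38.p14, used only for names and gene types: 22776 matched directly, 276 matched a synonym only and 1128 did not match.

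Total counts ranged from 34434993 to 38163152 per library. A count of 0 allows up to 3 counts, which is 0.0786 to 0.0871 CPM (counts scaled to a common library total) depending on the library; such limits, and the 95% Wilson intervals of shares, cover counting error only, since no molecular identifiers are described. Replicate pairs were compared by a chi-square statistic per degree of freedom over their counts. It ranged from 3.43 to 65.4, above 1 in every pair, so every pair differed by more than sampling noise and all 12 were kept as separate samples.

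Genes were tested with edgeR 4.0.16: TMM scaling factors (0.951 to 1.05), the filterByExpr filter with a minimum count of 10, which kept 15407 genes, and a quasi-likelihood fit of all 12 libraries with 1 mean per group, so that the 4 groups share 1 estimate of the spread (prior degrees of freedom 5.76, common biological coefficient of variation 0.117). Adjusted p-values are Benjamini-Hochberg values within a comparison, and genes with a value under 0.05 are called higher or lower. The 5 comparisons were BSG, M-BSG and M-BSG-Hot against NC, M-BSG against BSG, and M-BSG-Hot against M-BSG. Expression values are TMM-scaled CPM, given as mean ± SD over 3 libraries. Log2 fold changes of genes carry an approximate standard error (SE), the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. With 3 libraries per group a permutation test of a single gene cannot give a p under 0.1, so no such test is reported.

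Sets of genes were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the sets within a comparison. The 32 lists, holding 816 genes of which 795 are in the tables, covered heat shock, the integrated stress response, endoplasmic reticulum chaperones, the oxidative stress response, iron handling, the metal response, ferroptosis, p53 targets, apoptosis, DNA replication, mitosis, NF-kB inflammation, the interferon response, immediate-early genes, hypoxia and glycolysis, cholesterol synthesis, osteogenic genes, extracellular matrix, matrix proteases, autophagy, osmotic and pH transport, DNA repair, the proteasome, the cytosolic ribosome, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, nuclear-retained RNA, replication histones, and markers of immune, endothelial, epithelial and other mesenchymal cells. A set needed 5 tested members. Beside the number of members called over all genes stands the number called when adjusted over the list alone. Genes named in the text are the 8 highest and 8 lowest log2 fold changes per comparison among called genes with a mean of at least 5 CPM, an official-style symbol and groups that do not overlap, then up to 4 members with the smallest adjusted p of each list described, and 16 genes of heat, metal, growth and bone biology in both M-BSG-Hot comparisons, whatever their result. Some genes that this rule picks are not reported here. Groups, comparisons, tests, lists, this naming rule and the alternatives were set before the data were examined, except where an alternative or a test is said to have been added.

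The alternatives were edgeR with relative log expression (RLE) size factors or with library size only; no count filter beyond 1 count; a stricter filter of 10 counts in 3 libraries and a mean of 5 CPM; DESeq2 1.42.0; limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5; fits of only the 2 groups compared; the replicate number as a block; each library of the groups compared left out in turn; and, for lists, camera with an estimated inter-gene correlation and limma's fry. Added after the data were seen were leaving out each library of the other groups in turn, leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 together, removing each library's trend with gene length, scaling the lists by library size only, and a recount of shared calls under every alternative. Single named genes were not followed in the fits without 1 library of another group. Overlaps between comparisons that share the NC libraries were set beside 20 simulations of unchanged groups against the same NC counts. The other 9 divisions of each 6 libraries into 3 and 3 were also fitted.

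The edgeR and camera steps were tested on simulated data drawn from the gene means over all 12 libraries, their sizes and the fitted spread, with changes put into BSG. Each gene was drawn independently, so deviations that many genes of a library share are not covered by the numbers of false calls. Among 15187 genes, 52% of 50 genes changed 1.5-fold, 70% of 50 changed 2-fold, 94% of 50 changed 4-fold and 100% of 50 changed 8-fold were called, with 5 unchanged genes called. In the same simulated data M-BSG-Hot against M-BSG, with 0 changed genes, gave 0 calls. A list of 25 genes shifted by 0.5 on the log2 scale was called and 0 of 30 unshifted lists were. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The FPKM tables were used only for the limma alternatives and for gene lengths. Sequence reads were not used here.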

Results

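RNA was sequenced from 143B cells, an osteosarcoma line, in 12 libraries: 3 in each of the groups NC (the control), BSG, M-BSG and M-BSG-Hot. The series title names a borosilicate bioactive glass and magnetic hyperthermia for osteosarcoma, and the labels state neither the material and field given to each group nor the time of exposure. Total counts were 34434993, 36790336 and 36680546 in the NC libraries and 37593087, 37934039 and 37657383 in the BSG libraries. They were 37551563, 37266569 and 36505415 in M-BSG and 36881759, 37158430 and 38163152 in M-BSG-Hot. Between 18827 and 19599 gene symbols had at least 1 count in a library, and mitochondrial genes took 5.98% to 7.82% of counts.

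BSG 1 and M-BSG 1 stood apart from the other libraries of their groups, while the M-BSG-Hot libraries were spread out, with replicates 1 and 3 at the ends. The chi-square per degree of freedom between replicates was 65.4 for BSG 1 against BSG 2 and 60.3 for M-BSG 1 against M-BSG 2, and 7.87 for BSG 2 against BSG 3. Among the M-BSG-Hot libraries it was 43.1 for replicates 1 and 3, 16.3 for 1 and 2 and 18.9 for 2 and 3, and for NC 1 it was 10.4 and 9.07 against NC 2 and NC 3, which gave 3.43 against each other. Ribosomal protein genes took 8.36%, 7.71% and 7.81% of counts in NC, 11.3%, 8.37% and 9.14% in BSG, 9.91%, 7.51% and 8.10% in M-BSG, and 7.59%, 8.75% and 9.83% in M-BSG-Hot. The 95% Wilson intervals of these shares reach at most 0.0101 percentage points to either side. A principal component analysis put 34.8% of the variance on a first component, with the NC libraries at one end, and 15.1% on a second, along which replicates spread.

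**Figure D1:**
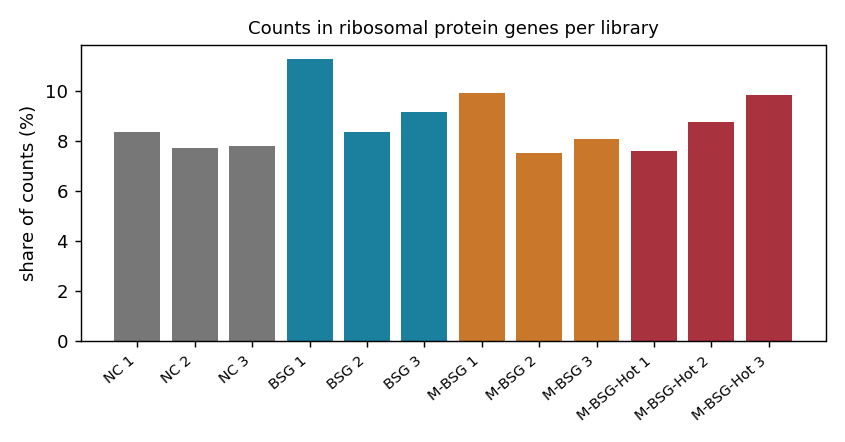
Percentage of each library's counts in genes for cytosolic ribosomal proteins, one bar per library, by group. BSG 1 at 11.3%, M-BSG 1 at 9.91% and M-BSG-Hot 3 at 9.83% are the highest of their groups.

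The comparison of BSG with NC asks, as far as the group names tell, what the BSG material alone did to the cells. FOS, which encodes a subunit of the AP-1 transcription factor, went from 4.33 ± 0.616 CPM in NC to 301.0 ± 19.3 in BSG (SD, n = 3 and 3), a log2 fold change of 6.12 (SE 0.183, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.24e-10). RASD1, a small GTPase induced by steroid hormone, rose by 7.08 on the log2 scale (SE 0.295, adjusted p = 3.9e-09) from 0.155 ± 0.0908 to 21.1 ± 1.07 CPM. ID2, an inhibitor of differentiation factors, rose from 1.42 ± 0.321 to 43.5 ± 5.4 CPM, by 4.93 on the log2 scale (SE 0.186, adjusted p = 1.93e-09). SNAI1, a repressor that drives loss of epithelial character, rose from 5.38 ± 0.945 to 86.4 ± 4.65 CPM, by 4.01 on the log2 scale (SE 0.153, adjusted p = 1.93e-09). NEAT1, the long RNA on which nuclear paraspeckles are built, fell from 162 ± 2.48 to 21.7 ± 3.49 CPM, a log2 fold change of -2.90 (SE 0.130, adjusted p = 7.96e-09).

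Among the other genes with the largest rises in BSG were FOSB, LSMEM1 and EGR2, with log2 fold changes of 5.50, 4.04 and 3.92. Of these FOSB and EGR2 encode transcription factors. The largest falls after NEAT1 were in SLC9A3-AS1 at -2.20, LENG8 at -1.80, MIR222HG at -1.75, GVQW3 at -1.56, ZNF780A at -1.41, ZNF589 at -1.38 and MIR23AHG at -1.34. For each of these genes the 3 BSG libraries lay beyond the 3 NC libraries. Because the strandedness of the counts is not given, values of antisense and host transcripts such as SLC9A3-AS1, MIR222HG and MIR23AHG are uncertain, since reads of an overlapping gene may be counted in them. The same holds for HSPA1A and HSPA1B, which are near-identical copies and share reads.

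Of the 29 heat shock genes tested, which encode chaperones for unfolded proteins, 16 were higher and 0 lower in BSG and 13 did not pass; adjusted over the list alone 19 were higher. HSPA2 rose by 2.57, HSPA1A by 1.61, HSPA1B by 1.49 and DNAJB1 by 0.97 on the log2 scale. The list was called up by camera (adjusted p = 6.87e-10), but not with an estimated correlation (adjusted p = 0.103 with an estimated correlation). Of 27 immediate-early genes, which cells can switch on soon after a stimulus, 19 were higher, 1 was lower and 7 did not pass, with 19 higher and 2 lower when adjusted over the list alone. They included SGK1 at 1.60 and KLF4 at 1.23, and the camera call (adjusted p = 6.94e-16) held with an estimated correlation (adjusted p = 0.0242). Of 24 NF-kB inflammation genes 10 were higher, 1 was lower and 13 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 7.97e-07; 0.0116 with an estimated correlation). NFKBIA, which encodes the inhibitor of NF-kB, rose by 2.08, PTGS2 by 1.70, NFKBIZ by 1.64 and IER3 by 1.00.

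Of 22 endoplasmic reticulum chaperone genes 6 were higher and 1 was lower, and 11 were higher and 1 lower when adjusted over the list alone. HSPA5 rose by 0.51 and DNAJB9 by 0.69, and DERL3 fell by 1.40; the camera adjusted p was 0.00118 (adjusted p = 0.104 with an estimated correlation). Of 29 apoptosis genes 7 were higher and 1 was lower, and 7 and 2 when adjusted over the list alone. They included the survival gene MCL1 at 0.60 and the death gene BCL2L11 at 0.70, with a camera adjusted p of 0.0245 (adjusted p = 0.104 with an estimated correlation). Of 24 cholesterol synthesis genes 3 were higher, with 3 adjusted over the list alone, including HMGCS1 at 0.84 and IDI1 at 0.68 (camera adjusted p = 0.00458; 0.343 with an estimated correlation). Of 14 replication histones 3 were higher, and 6 higher and 1 lower adjusted over the list alone, led by H2BC21 at 2.90 (camera adjusted p = 0.00191; 0.0779 with an estimated correlation). Of 13 genes of the mitochondrial genome 5 were higher and 6 adjusted over the list alone, including ND1 at 0.70 and ND2 at 0.57 (camera adjusted p = 0.000494; 0.343 with an estimated correlation). Of 29 extracellular matrix genes 1 was higher and 5 were lower, and 1 and 10 adjusted over the list alone; the list was called down (camera adjusted p = 0.000635; 0.379 with an estimated correlation). Its member COL6A3 fell by 0.54, a call lost without NC 2 (adjusted p = 0.108), NC 3 (0.105) or BSG 1 (0.0760).

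The proteasome, ribosome and oxidative phosphorylation lists were called up in BSG, beside the higher ribosomal protein share of BSG 1. At the preset correlation these lists stayed called without BSG 1, and also leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 together. Of 31 proteasome genes 5 were higher, and 24 adjusted over the list alone (camera adjusted p = 1.5e-08; 0.356 with an estimated correlation). Of 75 cytosolic ribosome genes 3 were higher, and 33 adjusted over the list alone (camera adjusted p = 4.67e-12; 0.433 with an estimated correlation, which was 0.934). Of 51 nuclear genes of oxidative phosphorylation 0 were called by edgeR (camera adjusted p = 2.72e-07; 0.444 with an estimated correlation). For the oxidative stress list, with 4 of 20 genes higher and 5 adjusted over the list alone, the camera adjusted p was 0.0353 (adjusted p = 0.343 with an estimated correlation). It was 0.0790 without BSG 3, 0.0805 without NC 2, 0.0522 without NC 3, 0.0943 with no count filter, 0.0585 with library size only and 0.0645 leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3. For the mitosis list, with 3 of 38 genes higher and 3 adjusted over the list alone, it was 0.0310 (adjusted p = 0.343 with an estimated correlation), and 0.113 without BSG 3, 0.0620 without NC 1, 0.0905 with no count filter and 0.0920 with library size only.

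The remaining lists were not called by camera in BSG against NC. Of 24 genes of the integrated stress response, which slows translation, 3 were higher, ATF3 at 1.40, PPP1R15A at 0.75 and ATF4 at 0.58, and 1 was lower (camera adjusted p = 0.297). Of 24 p53 targets 3 were higher, CDKN1A at 0.66, GADD45A at 0.74 and PPM1D at 0.62 (camera adjusted p = 0.160). Of 16 osteogenic genes 3 were higher, including TWIST1 at 0.75 and DLX3 at 1.90 (camera adjusted p = 0.0694). Of 31 hypoxia and glycolysis genes 2 were higher, ADM at 1.66 and SLC2A3 at 0.71, and 3 were lower (camera adjusted p = 0.940). Of 24 matrix proteases 2 were higher, including ADAMTS1 at 1.72 (camera adjusted p = 0.391), and of 33 autophagy genes 4 were higher, including MAP1LC3B at 0.51 and UVRAG at 0.49 (camera adjusted p = 0.0761). Of 38 DNA repair genes 2 were higher and 4 lower, including XRCC2, which fell by 1.04 (camera adjusted p = 0.297).

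Of 21 iron handling genes 2 were lower, including the mitochondrial importer SLC25A37, which fell by 0.69 (camera adjusted p = 0.831). Metal response genes gave 1 higher of 9 (camera adjusted p = 0.198) and ferroptosis genes 4 higher and 1 lower of 20 (0.302). DNA replication genes gave 2 higher of 38, including CCNE1 at 0.53 (0.374), and interferon genes 2 higher and 1 lower of 19 (0.815). Osmotic and pH transport genes gave 2 higher and 1 lower of 20, including the water channel AQP3 at 1.94 (0.957). Nuclear-retained RNAs gave 4 higher and 2 lower of 10, with MIR22HG at 1.66, SNHG12 at 1.21 and NEAT1 on opposite sides (0.160). Of 8 markers of other mesenchymal cells 1 was higher, COL2A1, and 1 was lower, SOX9 at -0.42 (0.957). The markers of immune, endothelial and epithelial cells had 2, 3 and 4 tested members, too few for a set test; CD14 rose by 1.74 from 0.539 to 1.80 CPM. Median, mean and camera direction differed in sign for 3 lists (DNA replication, interferon and other mesenchymal markers), none of them called.

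In total 847 genes were higher and 959 lower in BSG than in NC by edgeR's quasi-likelihood test, 284 and 234 of them by at least 2-fold, so that 46.9% of the called genes were higher (29.9% when scaled by library size only). Libraries of the groups did not overlap for 38.7% of genes, where chance gives 10%. The number higher was 1469 by DESeq2, 504 with the strict filter, 446 and 441 by limma and 1283 with the gene length trend removed, and without 1 library it was 520 (NC 1), 428 (NC 2), 424 (NC 3), 526 (BSG 1) and 1329 (M-BSG 1). The number lower was 572 without NC 1, 429 without NC 2, 452 without NC 3, 516 without BSG 1 and 625 without BSG 3. Of the 104 called genes picked by the naming rule 35 lost their call without 1 library or another, and 0 turned direction by edgeR in any alternative.

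**Figure D2:**
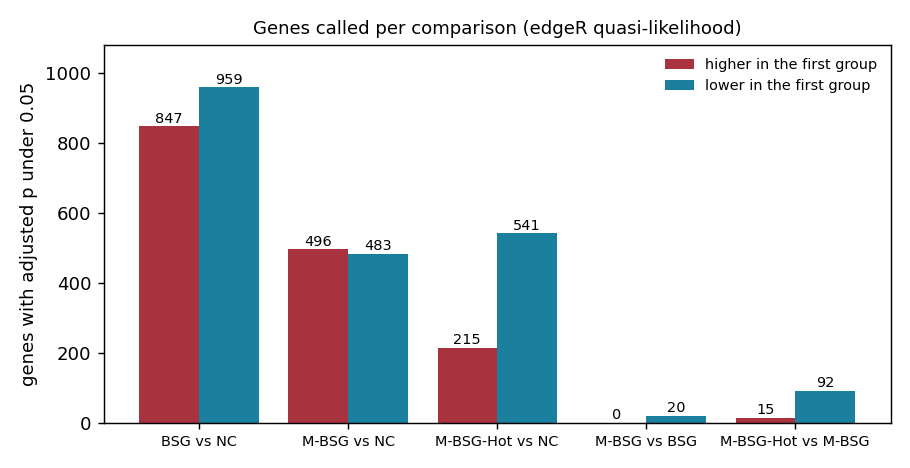
Number of genes called higher and lower at an adjusted p under 0.05 (vertical axis) in each comparison, by edgeR's quasi-likelihood test on 3 libraries per group. BSG against NC has the most, 847 higher and 959 lower, and M-BSG against BSG the fewest, 0 and 20.

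The comparison of M-BSG with NC asks, as far as the group names tell, what the material shared by M-BSG and M-BSG-Hot did without heating. Many of the genes that led in BSG led here too. FOS rose from 4.33 ± 0.616 to 243 ± 16.6 CPM (SD, n = 3 and 3), by 5.81 on the log2 scale (SE 0.181, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.88e-10). RASD1 rose by 5.64 (SE 0.308, adjusted p = 9.07e-08) to 7.75 ± 1.62 CPM, ID2 by 3.79 (SE 0.184, adjusted p = 3.26e-08) to 19.8 ± 3.2 CPM and SNAI1 by 3.09 (SE 0.149, adjusted p = 3.26e-08) to 45.7 ± 3.25 CPM. NEAT1 fell to 26.2 ± 3.33 CPM, a log2 fold change of -2.62 (SE 0.128, adjusted p = 3.26e-08). EGR1, a growth-factor-induced transcription factor, rose by 2.55 to 281 ± 42.5 CPM.

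FOSB, EGR2 and LSMEM1 rose by 5.20, 3.69 and 3.21 on the log2 scale. The other largest falls were in MIR222HG at -1.90, MIR23AHG at -1.37, LENG8 at -1.28, SLC9A3-AS1 at -1.27, GATD1 at -1.16, GVQW3 at -1.15 and ZNF780A at -1.15.

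Of 29 heat shock genes 8 were higher and 1 was lower in M-BSG, with the same counts adjusted over the list alone, including HSPA2 at 1.97, HSPA1B at 1.03, DNAJB1 at 0.82 and DNAJA1 at 0.49 (camera adjusted p = 2.29e-05; 0.259 with an estimated correlation). Of 27 immediate-early genes 17 were higher and 1 was lower, and 19 and 3 adjusted over the list alone (camera adjusted p = 2.17e-16; 0.0220 with an estimated correlation). Of 24 NF-kB genes 9 were higher and 0 lower, and 10 and 1 adjusted over the list alone, including NFKBIA at 1.84, PTGS2 at 1.87 and NFKBIZ at 1.35 (camera adjusted p = 6.45e-07; 0.00867 with an estimated correlation). Of 22 endoplasmic reticulum chaperone genes 3 were higher, and 3 adjusted over the list alone, HSPA5 at 0.41, HERPUD1 at 0.45 and DNAJB9 at 0.59 (camera adjusted p = 0.000151; 0.0895 with an estimated correlation). Apoptosis genes gave 5 higher and 1 lower of 29, and 6 and 1 adjusted over the list alone, including MCL1 at 0.69 and BCL2L11 at 0.69 (camera adjusted p = 0.0130; 0.0895 with an estimated correlation). Cholesterol synthesis gave 2 higher of 24, HMGCS1 at 0.86 and IDI1 at 0.55, and 2 adjusted over the list alone (camera adjusted p = 0.000108; 0.259 with an estimated correlation). The mitosis list had 1 of 38 genes higher, and 0 adjusted over the list alone (camera adjusted p = 0.00925; 0.275 with an estimated correlation).

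The mitochondrial genome had 4 of 13 genes higher, and 4 adjusted over the list alone, including ND1 at 0.61 (camera adjusted p = 0.000108; 0.278 with an estimated correlation). No gene passed edgeR's test among the proteasome, cytosolic ribosome and nuclear oxidative phosphorylation genes, over all genes or adjusted over the list alone. Camera called these lists up with an adjusted p of 0.000108 for the proteasome (adjusted p = 0.485 with an estimated correlation) and of 0.000108 for the ribosome (adjusted p = 0.684 with an estimated correlation). For oxidative phosphorylation it was 0.0318 (adjusted p = 0.746 with an estimated correlation). The ribosome call was lost without M-BSG 1 (adjusted p = 0.465), the library with the highest ribosomal protein share of its group, and leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 (0.325). The oxidative phosphorylation call was lost without M-BSG 1 (0.999), NC 2 (0.171) or NC 3 (0.0987), and turned down leaving out those 3 libraries (0.712). The other 18 lists were not called, and for iron handling, DNA replication and other mesenchymal markers the median, mean and camera direction differed in sign.

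In M-BSG 496 genes were higher and 483 lower than in NC by edgeR's quasi-likelihood test, 212 and 137 of them by at least 2-fold. Of the called genes 50.7% were higher (37.7% when scaled by library size only), and libraries did not overlap for 27.5% of genes against 10% by chance. The number higher was 318 with the strict filter, 310 and 305 by limma, 787 with the gene length trend removed and, without 1 library, 317 (NC 1), 295 (NC 2), 306 (NC 3) and 327 (M-BSG 3). The number lower was 261 without NC 1, 248 without NC 2, 254 without NC 3, 312 without M-BSG 2 and 255 without M-BSG 3; leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 gave 1047 higher and 925 lower.

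The comparison of M-BSG-Hot with NC asks what that material did together with heating, as the group name has it. RASD1 rose from 0.155 ± 0.0908 to 14.8 ± 3.12 CPM (SD, n = 3 and 3), by 6.57 on the log2 scale (SE 0.298, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.54e-08). FOS rose by 5.11 (SE 0.177, adjusted p = 1.6e-09) to 149 ± 35.0 CPM and ID2 by 4.78 (SE 0.185, adjusted p = 3.75e-09) to 39.1 ± 4.93 CPM. H2BC21, a histone gene also expressed outside DNA replication, rose from 2.12 ± 0.191 to 13.9 ± 2.4 CPM, by 2.71 (SE 0.202, adjusted p = 2.53e-06). NEAT1 fell to 22.0 ± 2.86 CPM, by 2.88 on the log2 scale (adjusted p = 1.54e-08). The heat-inducible chaperone HSPA1A rose from 10.6 ± 1.21 to 23.2 ± 3.37 CPM, by 1.13 (SE 0.120, adjusted p = 7.45e-05).

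FOSB, SNAI1 and LSMEM1 rose by 3.68, 2.94 and 2.51. The other largest falls were in MIR23AHG at -2.27, LENG8 at -1.68, KCNQ1OT1 at -1.61, SLC9A3-AS1 at -1.54, GVQW3 at -1.49, ZNF789 at -1.41 and D2HGDH at -1.36. Of the 16 genes of heat, metal, growth and bone biology, HSPA1A, HSPA1B (0.93, adjusted p = 0.000749), ATF3 (0.93, adjusted p = 0.00378) and DNAJB1 (0.31, adjusted p = 0.0328) passed edgeR's test. The DNAJB1 call was lost without NC 2 (adjusted p = 0.143), NC 3 (0.173), M-BSG-Hot 2 (0.0694) or M-BSG-Hot 3 (0.113), and when scaled by library size only (0.0943). The remaining 12 did not pass edgeR's test: HSPA6, HMOX1, TFRC, FTH1, DDIT3, CDKN1A, MKI67, RUNX2, ALPL, COL1A1, MT2A and VEGFA, with log2 fold changes from -0.56 for DDIT3 to 0.62 for HSPA6. VEGFA, at -0.31 (adjusted p = 0.0575), passed with library size only (0.0209), by DESeq2 (0.0168), by limma (0.0167 and 0.0184), with the length trend removed (0.0153), leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 (0.0105) and without M-BSG-Hot 2 (0.0408). DDIT3 passed with the length trend removed (0.0116) and leaving out the 3 libraries (0.00279), and CDKN1A without M-BSG-Hot 1 (0.0368).

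Of 29 heat shock genes 5 were higher and 0 lower in M-BSG-Hot, and 9 were higher adjusted over the list alone, with HSPA2 at 1.75 (camera adjusted p = 2.53e-06; 0.224 with an estimated correlation). Of 27 immediate-early genes 13 were higher, and 18 adjusted over the list alone, including SGK1 at 1.43 and KLF4 at 0.99 (camera adjusted p = 4.36e-16; 0.0155 with an estimated correlation). Of 24 NF-kB genes 7 were higher, and 12 adjusted over the list alone, including NFKBIA at 1.26 and CXCL1 at 1.54 (camera adjusted p = 1.62e-07; 0.00352 with an estimated correlation). Of 24 matrix proteases 3 were higher, and 3 adjusted over the list alone, with ADAMTS1 at 1.60 (camera adjusted p = 0.000458; 0.0313 with an estimated correlation). Of 14 replication histones 6 were higher, and 7 adjusted over the list alone (camera adjusted p = 5.1e-09; 0.00352 with an estimated correlation). Their median log2 change was 0.84 with sums under 3 counts over a group set to 3, and all 14 were positive; 2 genes were so set. H1-5 had 0 counts in the 3 NC libraries together and 106 in M-BSG-Hot, at least 5.15 higher on the log2 scale against 3 counts over the group; H3C2 had 1 and 48 counts and H1-4 had 10 and 135. Only 2 of the 14 histone genes had a mean of at least 5 CPM.

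Endoplasmic reticulum chaperones gave 1 higher and 1 lower of 22, and the same adjusted over the list alone (camera adjusted p = 0.0115; 0.224 with an estimated correlation). Cholesterol synthesis gave 1 higher of 24, HMGCS1 at 0.46, and 2 adjusted over the list alone (camera adjusted p = 3.31e-05; 0.224 with an estimated correlation). Autophagy gave 1 of 33, and 1 adjusted over the list alone (camera adjusted p = 0.00365; 0.264 with an estimated correlation). The mitochondrial genome gave 3 of 13, and 3 adjusted over the list alone (camera adjusted p = 0.00503; 0.480 with an estimated correlation). By edgeR 0 genes passed in 4 further lists that camera called up, over all genes or adjusted over the list alone. Their camera adjusted p was 6.68e-06 for the proteasome (0.505 with an estimated correlation), 8.49e-07 for the ribosome (0.595) and 7.86e-05 for oxidative phosphorylation (0.595), beside a ribosomal protein share that was highest in M-BSG-Hot 3. For oxidative stress it was 0.0162 (0.264 with an estimated correlation), lost without M-BSG-Hot 1 (0.103). The proteasome, ribosome and oxidative phosphorylation lists stayed called at the preset correlation without M-BSG-Hot 3. Nuclear-retained RNAs had 2 higher and 4 lower of 10, including MALAT1 at -0.67, and were not called (0.416); for iron handling, DNA replication and osmotic transport the median, mean and camera direction differed in sign.

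In M-BSG-Hot 215 genes were higher and 541 lower than in NC by edgeR's quasi-likelihood test, 89 and 212 of them by at least 2-fold. Of the called genes 28.4% were higher (18.1% when scaled by library size only), and libraries did not overlap for 28% of genes against 10% by chance. The number higher was 397 by DESeq2, 118 with the strict filter, 107 and 118 by limma, 386 with the gene length trend removed and, without 1 library, 126 (NC 1), 103 (NC 2), 115 (NC 3) and 135 (M-BSG-Hot 3). The number lower was 320 with the strict filter and, without 1 library, 341 (NC 1), 285 (NC 2), 308 (NC 3), 327 (M-BSG-Hot 1) and 331 (M-BSG-Hot 3); leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 gave 451 higher and 862 lower.

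**Figure D3:**
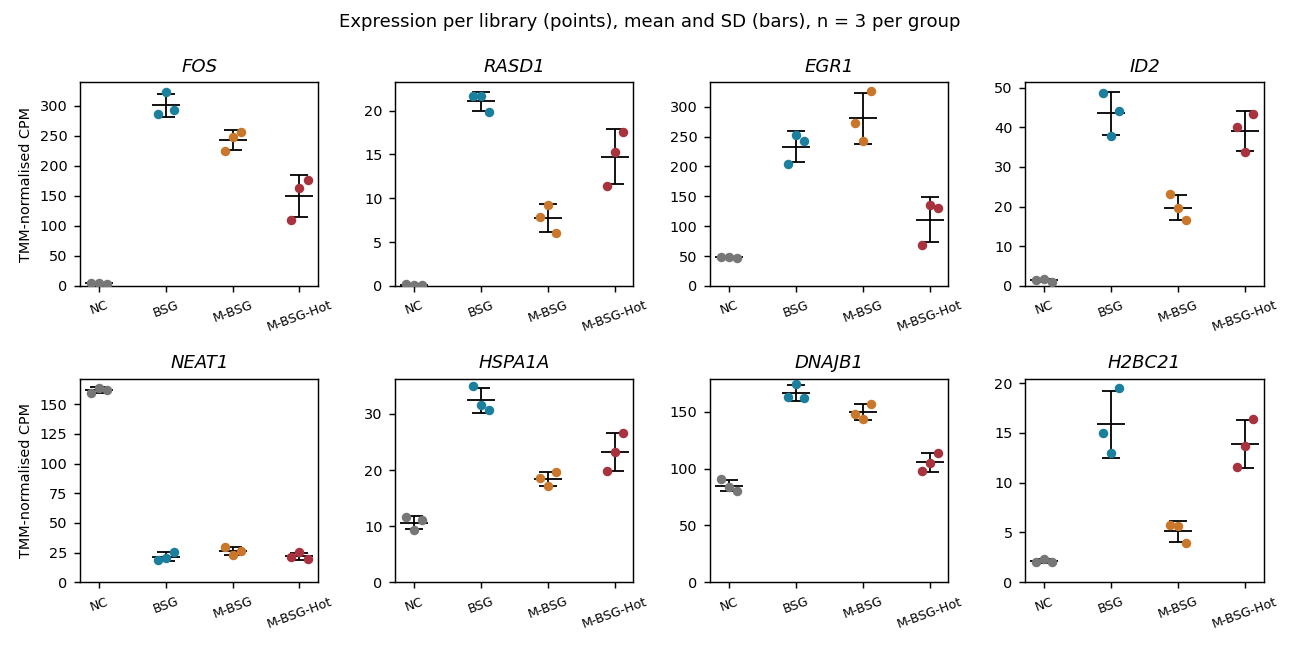
TMM-scaled CPM of FOS, RASD1, EGR1, ID2, NEAT1, HSPA1A, DNAJB1 and H2BC21 in the 12 libraries, one panel per gene; points are libraries and bars the mean and SD of the 3 libraries of a group. FOS is at 3.73 to 4.96 CPM in the NC libraries and at 109 to 323 CPM in all others, while H2BC21 is higher in BSG and M-BSG-Hot than in M-BSG.

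The comparison of M-BSG with BSG asks what sets the response to the M-BSG material apart from that to BSG. The 20 genes called were all lower in M-BSG. H2BC21 fell from 15.8 ± 3.37 to 5.10 ± 1.04 CPM (SD, n = 3 and 3), a log2 fold change of -1.63 (SE 0.186, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00268). RGS2, a brake on G-protein signalling, fell by 1.03 (SE 0.105, adjusted p = 0.00138) from 43.5 to 21.3 CPM. RASD1 fell by 1.44 (adjusted p = 0.00471), ID2 by 1.14 (0.00471), SNAI1 by 0.92 (0.00940), HSPA1A by 0.81 (0.00940), CITED2 by 0.75 (0.00471), HEXIM1 by 0.60 (0.00940) and KLF4 by 0.55 (0.0116). Of the 9 genes named here, all but H2BC21 and RGS2 lost their call in at least 1 of the alternatives followed for single genes. Without M-BSG 3 the adjusted p was 0.0558 for RASD1, 0.0568 for ID2, 0.0837 for SNAI1, 0.0568 for HSPA1A, 0.0568 for CITED2, 0.0937 for HEXIM1 and 0.0937 for KLF4. HSPA1A also lost it without M-BSG 2 (0.0710), HEXIM1 without BSG 3 (0.0526) or M-BSG 2 (0.0532), and KLF4 without BSG 2 (0.0709) or M-BSG 2 (0.0958).

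Of 29 heat shock genes 1 was lower, HSPA1A, and 3 were lower adjusted over the list alone; camera called the list down (adjusted p = 3.19e-09; 0.232 with an estimated correlation). Of 27 immediate-early genes 1 was lower, and 6 adjusted over the list alone (camera adjusted p = 7.91e-05; 0.416 with an estimated correlation). Of 14 replication histones 1 was lower, and 1 adjusted over the list alone (camera adjusted p = 0.000726; 0.132 with an estimated correlation). By edgeR 0 genes passed in the integrated stress response, extracellular matrix, proteasome, ribosome and oxidative phosphorylation lists, over all genes or adjusted over the list alone. The integrated stress response was called down (camera adjusted p = 0.0220; 0.789 with an estimated correlation), as were the proteasome (7.91e-05), ribosome (3.02e-09) and oxidative phosphorylation lists (2.56e-07), each at 0.789 with an estimated correlation. Extracellular matrix was called up (0.00112; 0.789 with an estimated correlation). Without BSG 1, the library with the highest ribosomal protein share, the adjusted p was 0.131 for the ribosome, 0.312 for the proteasome, 0.184 for oxidative phosphorylation and 0.125 for extracellular matrix, which was also lost without M-BSG 2 (0.0905). The integrated stress response was lost without BSG 2 (0.186), BSG 3 (0.159) or M-BSG 2 (0.339) and with no count filter (0.0721). Of the lists not called, 6 had a median, mean and camera direction that differed in sign.

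By edgeR's quasi-likelihood test 0 genes were higher and 20 lower in M-BSG than in BSG, 15 of the latter by at least 2-fold; 1042 genes had an unadjusted p under 0.05 in either direction, and DESeq2 called 13 higher and 37 lower. Libraries of the groups did not overlap for 8.9% of genes, where chance gives 10%. Without 1 library the number higher was 1 (BSG 2), 1 (BSG 3), 3 (M-BSG-Hot 1) and 1 (M-BSG-Hot 3), and the number lower 13 (BSG 3), 13 (M-BSG 1), 11 (M-BSG 2) and 3 (M-BSG 3). Leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 gave 73 higher and 38 lower, no count filter 6 and 32, and the strict filter 9 lower.

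The comparison of M-BSG-Hot with M-BSG asks, as far as the group names tell, what heating added to the M-BSG material, the question behind the hyperthermia of the series title. The inducible chaperone gene DNAJB1 fell from 150 ± 6.73 CPM in M-BSG to 106 ± 8.32 in M-BSG-Hot (SD, n = 3 and 3), by 0.51 on the log2 scale (SE 0.078, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00864). The early transcription factors EGR1, at -1.34 (SE 0.199, adjusted p = 0.00767), and FOSB, at -1.52 (SE 0.227, adjusted p = 0.00773), fell from 281 to 111 and from 84.6 to 29.4 CPM. H2BC21 rose from 5.10 to 13.9 CPM, by 1.45 (SE 0.186, adjusted p = 0.00478), and ID2 from 19.8 to 39.1 CPM, by 0.98 (SE 0.145, adjusted p = 0.00749). CXCR4, a chemokine receptor used in migration, rose from 16.1 to 26.1 CPM, by 0.70 (SE 0.107, adjusted p = 0.00831). The DNAJB1 call was lost without M-BSG 3 (adjusted p = 0.0777) or M-BSG-Hot 1 (0.0580), the ID2 call without M-BSG 3 (0.0553), and with only the 2 groups fitted the adjusted p was 0.0627 for EGR1 and FOSB, 0.0687 for CXCR4 and 0.0689 for DNAJB1.

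Of the 16 genes of heat, metal, growth and bone biology DNAJB1 alone passed edgeR's test. CDKN1A, at -0.37 (adjusted p = 0.162), passed by DESeq2 (0.0350), with the length trend removed (0.0102) and leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 (0.0144). HSPA1A changed by 0.33 (adjusted p = 0.350), HSPA1B by -0.11 (0.893), HMOX1 by -0.03 (0.983), TFRC by -0.03 (0.982) and FTH1 by 0.10. HSPA6 had 5 to 13 counts in each of these 6 libraries, and no difference was detectable at this depth. DDIT3, ATF3, MKI67, RUNX2, ALPL, COL1A1, MT2A and VEGFA had log2 fold changes between -0.45 for RUNX2 and 0.13 for DDIT3. Other genes with the largest rises were RASD1 at 0.93, ZSCAN32 at 0.47, CCN1 at 0.38 and GALNT18 at 0.36. RASD1 lost its call without M-BSG 1 (adjusted p = 0.0652), M-BSG 3 (0.197), M-BSG-Hot 2 (0.114) or M-BSG-Hot 3 (0.145). Further falls were in KCNQ1OT1 at -1.83, SNHG4 at -1.61, RASL11A at -1.46, ZFP36 at -1.32, ZNF92 at -1.29 and ARID5B at -1.22. Values of KCNQ1OT1 and SNHG4, an antisense and a host transcript, carry the uncertainty of strand, and KCNQ1OT1 lost its call without M-BSG 3 (0.0724) or M-BSG-Hot 1 (0.0823). Of the 27 called genes picked by the naming rule in this comparison, 19 lost their call without 1 library or another of the 2 groups, ZSCAN32, CCN1, GALNT18 and ARID5B among them. H2BC21, SNHG4, RASL11A and ZNF92 kept their call in every alternative followed for single genes, which did not include the fits without 1 NC or BSG library.

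Of 14 replication histones 3 were higher in M-BSG-Hot than in M-BSG and 0 lower, and 7 were higher adjusted over the list alone (camera adjusted p = 1.61e-10; 0.00299 with an estimated correlation). Their median log2 change in summed counts was 1.29, with 13 positive and 1 negative. Only 2 of the 14 had a mean of at least 5 CPM. H1-5 had 5 counts over the M-BSG libraries and 106 over M-BSG-Hot, and H1-4 had 13 and 135. Of 38 DNA replication genes 0 passed edgeR's test, and that list was not called (camera adjusted p = 0.829). The calls of H1-5 and H1-4 were each lost without M-BSG 2 (adjusted p = 0.129 and 0.161), M-BSG 3 (0.165 and 0.208), M-BSG-Hot 1 (0.120 and 0.140), M-BSG-Hot 2 (0.0902 and 0.115) or M-BSG-Hot 3 (0.0680 and 0.0577). Of 10 nuclear-retained RNAs 3 were lower, KCNQ1OT1, MIR22HG at -0.72 and SNHG12 at -0.52, and 6 adjusted over the list alone (camera adjusted p = 1.61e-06; 0.0830 with an estimated correlation). MIR22HG lost its call without M-BSG 3 (0.0829) and with only the 2 groups fitted (0.101). SNHG12 lost it without M-BSG 1 (0.132), M-BSG 2 (0.0886), M-BSG 3 (0.156), M-BSG-Hot 1 (0.218) or M-BSG-Hot 2 (0.141), with the strict filter (0.0578), with only the 2 groups fitted (0.155) and with the replicate block (0.0608). Of 24 matrix proteases 0 passed edgeR's test, also adjusted over the list alone, and camera called the list up (adjusted p = 0.00600; 0.0830 with an estimated correlation). Of 29 extracellular matrix genes 1 was higher, CCN1, and 1 adjusted over the list alone. The list was called up (camera adjusted p = 0.00243; 0.597 with an estimated correlation), but not without M-BSG 1 (0.327) or leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 (0.143).

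Of 27 immediate-early genes 1 was higher and 6 were lower, and 5 and 11 adjusted over the list alone, with EGR1, FOSB and ZFP36 falling. The list was called down (camera adjusted p = 0.0453; 0.592 with an estimated correlation) and lost without BSG 1 (0.0554), BSG 2 (0.0531), BSG 3 (0.0677), M-BSG 2 (0.0871), M-BSG 3 (0.0641), M-BSG-Hot 1 (0.0667) or NC 2 (0.0510). Of 29 heat shock genes 0 were higher and 1 was lower by edgeR, and 1 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.917). Of 29 apoptosis genes 2 were lower, MCL1 at -0.51 and BCL2L11 at -0.70 (camera adjusted p = 0.232). MCL1 lost its call without M-BSG 3 (adjusted p = 0.0724) or M-BSG-Hot 1 (0.0562), and with only the 2 groups fitted (0.0719). BCL2L11 lost it without M-BSG 2 (0.0899), M-BSG 3 (0.216), M-BSG-Hot 1 (0.184), M-BSG-Hot 2 (0.0511) or M-BSG-Hot 3 (0.138), with library size only (0.0632), with only the 2 groups fitted (0.0696) and by limma (0.102 and 0.0939). The NF-kB list gave 1 lower of 24, NFKBIA at -0.57 (0.917), and hypoxia genes 2 lower of 31, ADM at -0.51 and SLC2A3 at -0.54 (0.245). NFKBIA, ADM and SLC2A3 each lost their call without M-BSG 3 (0.156, 0.0802 and 0.0992) or M-BSG-Hot 1 (0.120, 0.0869 and 0.0869), and with only the 2 groups fitted (0.0931, 0.0774 and 0.0627). NFKBIA also lost it without M-BSG 1 (0.0571), M-BSG 2 (0.0810) or M-BSG-Hot 2 (0.0819), and SLC2A3 without M-BSG 2 (0.0661). Iron handling gave 0 of 21 by edgeR (0.917). Median, mean and camera direction differed in sign for 9 of the 24 lists not called, heat shock, iron handling and NF-kB among them.

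By edgeR's quasi-likelihood test 15 genes were higher and 92 lower in M-BSG-Hot than in M-BSG, 9 and 36 of them by at least 2-fold. DESeq2 called 47 and 229, a fit of only the 2 groups 3 and 7, removal of the gene length trend 35 and 178, and leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 gave 29 and 246; 1362 genes had an unadjusted p under 0.05. Libraries of the groups did not overlap for 13.8% of genes, where chance gives 10%. Without 1 library the number higher was 9 (NC 1), 8 (NC 2), 8 (NC 3), 5 (M-BSG 2), 3 (M-BSG 3), 8 (M-BSG-Hot 1), 6 (M-BSG-Hot 2) and 7 (M-BSG-Hot 3). The number lower was 55 (NC 1), 52 (NC 2), 47 (NC 3), 56 (BSG 3), 45 (M-BSG 2), 22 (M-BSG 3), 27 (M-BSG-Hot 1) and 60 (M-BSG-Hot 3).

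The changes against NC overlapped between groups. BSG and M-BSG shared 425 genes higher and 391 lower, with 0 called in opposite directions by edgeR, where independent calls would give 27.3 and 30.1. Unchanged groups simulated against the same NC counts gave 0 and 0 shared calls, but with no changed gene hardly any call can arise. This cannot show how many calls become shared through the NC libraries when many genes change. The simulation also drew the other libraries independently, while the deviations of BSG 1 and M-BSG 1 were correlated (r = 0.408). Across 15407 genes, which are not independent replicates, the log2 fold changes of BSG and M-BSG had Pearson's r = 0.869 and a covariance of 0.327, of which the simulation gave 0.524 and 0.0402, a difference in covariance of 0.287. BSG and M-BSG-Hot shared 181 higher and 425 lower (independent 11.8 and 33.7), with r = 0.819 and a covariance 0.252 above the simulated one. M-BSG and M-BSG-Hot shared 174 higher and 315 lower (independent 6.92 and 17.0) and had 1 gene in opposite directions, with r = 0.809 and a covariance 0.206 above the simulated one. Since the 3 NC libraries enter each comparison and cannot be divided between them, part of each overlap may come from the shared controls. The 816 calls shared by BSG and M-BSG were 524 without NC 1, 454 without NC 2, 483 without NC 3 and 533 without M-BSG 3.

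The comparisons of BSG with NC and of M-BSG-Hot with M-BSG share no library, but they come from 1 fit with 1 estimate of each gene's spread. BSG 1 and M-BSG 1 also deviated alike from their group mates (r = 0.408), which pushes the 2 comparisons in opposite directions. Numbers for independent calls allow for neither. Of the 77 calls shared by the 2 comparisons 64 were higher in BSG and lower in M-BSG-Hot (5.06 if independent) and 1 was the reverse (0.934). Of the others 6 were higher in both (0.825) and 6 lower in both (5.73). Across all 15407 genes there was little opposition, with r = -0.154, a covariance of -0.035 and the same sign in 49.2%. FOSB, EGR1, ZFP36, MCL1, NFKBIA and DNAJB1 were among the 64, and ID2, RASD1 and H2BC21 among the 6 higher in both. With only the 2 groups of each comparison fitted the 77 were 7, of which 5 were opposite, and by DESeq2 194, of which 156 were opposite. Leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 together, 139 of 184 shared calls were opposite (r = -0.135 across genes). Without M-BSG 1 alone 49 of 61 were opposite (r = -0.079), and without BSG 1 alone 83 of 100 (r = -0.141). Without 1 library the 77 were 44 (NC 1), 41 (NC 2), 38 (NC 3), 50 (BSG 2), 47 (BSG 3), 34 (M-BSG 2), 16 (M-BSG 3), 24 (M-BSG-Hot 1), 51 (M-BSG-Hot 2) and 46 (M-BSG-Hot 3).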

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

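The test that leaves out BSG 1, M-BSG 1 and M-BSG-Hot 3 together was added after they were seen to have the highest ribosomal protein shares of their groups. The change against NC differed between M-BSG-Hot and M-BSG for 107 genes and between BSG and M-BSG for 20 genes in the main fit. In place of the 107, 10 genes were called with only the 2 groups fitted, 25 without M-BSG 3 and 276 by DESeq2. In place of the 20, 3 were called without M-BSG 3 and 50 by DESeq2. Each difference was tested directly, by the edgeR comparison of M-BSG-Hot with M-BSG and of M-BSG with BSG, which is the same as the difference of their changes against NC. In the heated step 15 of the 107 were higher and 92 lower, H2BC21 with a log2 fold change of 1.45 and EGR1 with -1.34 among them, and all 20 genes of the other step, such as RGS2 at -1.03, were lower in M-BSG than in BSG.

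Among the 5 lists called in the heated step, replication histones were called up, with 3 of 14 genes higher, and immediate-early genes down, with 6 of 27 lower and 1 higher; the latter call (adjusted p = 0.0453) was 0.592 with an estimated correlation and was lost without NC 2 (0.0510), BSG 1 (0.0554), BSG 2 (0.0531), BSG 3 (0.0677), M-BSG 2 (0.0871), M-BSG 3 (0.0641) or M-BSG-Hot 1 (0.0667). Without BSG 1, M-BSG 1 and M-BSG-Hot 3 the mean log2 fold change of the 14 histones was 1.74 (camera adjusted p = 3.12e-07), and 1.48 with all libraries. This argues against those libraries as the cause of the histone rise, though only 2 of the 14 genes had a mean of at least 5 CPM. The mean of the 27 immediate-early genes was then -0.37 (camera adjusted p = 0.0293), and -0.31 with all libraries. That fit kept M-BSG-Hot 1, where EGR1 was at 67.7 CPM, against 135.5 in M-BSG-Hot 2 and 129.9 in M-BSG-Hot 3. It therefore cannot tell whether a single deviating library gave the immediate-early fall. A greater carry-over of RNA without a poly(A) tail, which most histone transcripts lack, cannot be told apart from a rise of the histones themselves. Small structural RNAs had a median log2 fold change of -0.042 (SE 0.096), below what that carry-over would give, but only 2 such genes were abundant enough to test, too few for a verdict. The heating that the group name states may also act on these genes, which remains untested because the labels give one treatment text for every sample.

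The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, and in what follows the number of splits with a result as large counts the real one. Every other split also mixes the groups on both sides, so a real difference between groups raises the spread and makes calls less likely. Low numbers in the other splits therefore cannot exclude chance. In BSG against NC 1 split gave as many as the real 847 higher, and 1 as many as the 959 lower, the highest other split having 0 calls in one direction. The same numbers, 1 split and a highest other of 0, belong to the 496 higher and 483 lower of M-BSG and to the 215 higher and 541 lower of M-BSG-Hot. In M-BSG-Hot against M-BSG 1 split gave as many as the real 15 higher and 1 as many as the 92 lower, with a highest other of 1. In M-BSG against BSG all 10 splits gave at least the 0 higher and 2 gave at least the 20 lower, with a highest other of 697. That split, of BSG 1, BSG 3 and M-BSG 1 against BSG 2, M-BSG 2 and M-BSG 3, called 1388 genes, which points to a structure of the samples other than their groups.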

How the results depend on the processing

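Leaving out BSG 1, M-BSG 1 and M-BSG-Hot 3 together, leaving out libraries of groups outside a comparison, removing the gene length trend, scaling lists by library size only and recounting shared calls were chosen after the data were seen. No called gene was called in the opposite direction in any alternative, and 1 call of BSG against NC had the opposite sign, though no call, with the length trend removed. Named genes were not followed in the fits without 1 library of another group. Over all named genes and the other alternatives, 4414 values kept their direction and their side of the threshold, and 573 were no longer past it. A further 13 newly passed it and 23 turned direction, none of the 23 for a called gene. The 4414 include uncalled genes that stayed uncalled. Of the called genes picked by the naming rule, 40 of 104 for BSG, 24 of 77 for M-BSG and 17 of 56 for M-BSG-Hot against NC lost the call in at least 1 alternative. So did 7 of 9 for M-BSG against BSG and 23 of 27 for M-BSG-Hot against M-BSG. No list called turned direction with RLE factors or library size only. Depth limits rare transcripts, such as HSPA6 with 2 to 19 counts per library. Except where fewer genes or libraries enter by construction, the cause was not tested.

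With the strict filter, which tests fewer genes, the number higher was 504 for BSG against NC, 318 for M-BSG against NC, 118 for M-BSG-Hot against NC and 7 for M-BSG-Hot against M-BSG. The number lower was 320 for M-BSG-Hot against NC and 9 for M-BSG against BSG, and the calls shared by BSG and M-BSG were 536. With no count filter M-BSG against BSG gave 6 higher and 32 lower. DESeq2 gave 1469 higher for BSG against NC, 397 higher for M-BSG-Hot against NC, 13 higher and 37 lower for M-BSG against BSG, and 47 higher and 229 lower for M-BSG-Hot against M-BSG. The calls shared by BSG against NC and M-BSG-Hot against M-BSG were then 194. With limma on log2(FPKM + 1) the number higher was 446, 310 and 107 for BSG, M-BSG and M-BSG-Hot against NC and 1 for M-BSG against BSG. With log2(FPKM + 0.1) it was 441, 305, 118 and 1, and 7 for M-BSG-Hot against M-BSG. M-BSG against BSG had 1 higher with library size only and 2 with the replicate block. Fitting only the 2 groups compared gave 3 higher and 7 lower for M-BSG-Hot against M-BSG and 7 calls shared with BSG against NC.

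With the length trend removed the number higher was 1283, 787 and 386 for BSG, M-BSG and M-BSG-Hot against NC and 3 for M-BSG against BSG. M-BSG-Hot against M-BSG then gave 35 higher and 178 lower, with 155 calls shared with BSG against NC. Leaving out the 3 libraries gave 1047 higher and 925 lower for M-BSG against NC, 451 and 862 for M-BSG-Hot against NC, 73 and 38 for M-BSG against BSG, and 29 and 246 for M-BSG-Hot against M-BSG, with 184 calls shared with BSG against NC. With an estimated correlation camera called 2 lists for BSG, 2 for M-BSG and 4 for M-BSG-Hot against NC, 0 for M-BSG against BSG and 1 for M-BSG-Hot against M-BSG. By fry, which does not compare a list with other genes, 2 were called for M-BSG against BSG.

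Leaving out 1 of the 12 libraries at a time, BSG against NC ranged from 424 to 1329 higher, 429 to 1227 lower and 12 to 15 lists. M-BSG against NC ranged from 295 to 635 higher, 248 to 575 lower and 10 to 13 lists, and M-BSG-Hot against NC from 103 to 304 higher, 285 to 654 lower and 12 to 13 lists. M-BSG against BSG ranged from 0 to 3 higher, 3 to 24 lower and 4 to 9 lists, and M-BSG-Hot against M-BSG from 3 to 20 higher, 22 to 123 lower and 4 to 8 lists. The calls shared by BSG and M-BSG ranged from 454 to 822, and those shared by BSG against NC and M-BSG-Hot against M-BSG from 16 to 100.

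The genes that turned direction were uncalled ones of the 16 fixed for the heated group. In M-BSG-Hot against NC the log2 fold change of TFRC was -0.018 with library size only, -0.036 and -0.037 by limma with a pseudocount of 1 and 0.1, and -0.125 to 0.173 leaving out 1 library. In M-BSG-Hot against M-BSG, HMOX1 was 0.148 and ALPL 0.099 without the 3 libraries. Leaving out 1 library, this comparison gave -0.268 to 0.015 for HSPA1B, -0.411 to 0.458 for HSPA6, -0.205 to 0.149 for HMOX1, -0.203 to 0.098 for TFRC and -0.101 to 0.355 for DDIT3. It gave -0.278 to 0.069 for ATF3, -0.207 to 0.048 for MKI67, -0.265 to 0.073 for ALPL, -0.063 to 0.247 for MT2A and -0.150 to 0.024 for VEGFA.

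Replicate numbers were not taken as pairs, since the labels do not give them as such. Deviations of libraries with the same number had correlations across genes of 0.408, 0.215 and 0.073 between M-BSG and BSG, 0.174, 0.036 and 0.075 between BSG and NC, and 0.183, 0.076 and 0.059 between M-BSG and NC. They were -0.287, -0.005 and -0.078 between M-BSG-Hot and M-BSG, and -0.104, 0.030 and -0.069 between M-BSG-Hot and NC. With the number as a block BSG against NC gave 1017 higher and 1083 lower.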

Other observations

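The gene families described here, and the test on nuclear-retained RNAs, were chosen after the results were seen. Camera p-values of the families were adjusted over all families and comparisons together, not within a comparison. Antisense, divergent and intronic transcripts, recognised by their symbol endings, numbered 670 among the tested genes. Of these 79 were lower in BSG, 59 in M-BSG and 69 in M-BSG-Hot than in NC, while 13, 12 and 0 were higher by edgeR, with camera adjusted p of 0.000478, 1.11e-07 and 9.28e-11 (0.277, 0.171 and 0.138 with an estimated correlation). Of 397 zinc finger genes with ZNF symbols, a class of mostly repressive DNA-binding proteins, 54 were lower in BSG, 24 in M-BSG and 33 in M-BSG-Hot, while 13, 13 and 3 were higher, with camera adjusted p of 0.000377, 0.0349 and 6e-06 (0.277, 0.443 and 0.271 with an estimated correlation). ZNF780A fell in BSG, with a log2 fold change of -1.41.

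Of 28 tested host genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, 9 were higher and 1 was lower in BSG than in NC, and likewise 9 and 1 in M-BSG, with camera adjusted p of 0.000242 and 0.000270 (0.366 for each with an estimated correlation). In M-BSG-Hot 1 was higher and 3 were lower than in NC, with a median log2 fold change of 0.08 (camera adjusted p = 0.740), and 4 were lower than in M-BSG (camera adjusted p = 4.22e-07; 0.277 with an estimated correlation), SNHG4 at -1.61 among them. The values of antisense and host transcripts are uncertain because strand is not given. No family turned direction with RLE factors or library size only, and the unadjusted camera p of the zinc finger genes in M-BSG against NC was 0.0587 with library size only.

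Long non-coding RNA genes were compared with protein-coding genes alone, which left 14948 of the 15407 tested genes. They were over-represented among the genes of these types lower in BSG than in NC, at 201 of 926 (21.7%) where they were 11.1% of the 14948. The odds ratio was 2.38 (95% interval 2.01 to 2.82, Fisher's exact test). With the gene length trend removed from each library the odds ratio was 2.80 (2.39 to 3.27), which argues against that trend as the cause. The median log2 fold change of long non-coding genes was -0.17, below the range of -0.05 to -0.01 that held the central 95% of 10000 lists of protein-coding genes matched on expression, which argues against low expression. A lower yield of nuclear RNA as a whole cannot be told apart: the 9 nuclear-retained RNAs other than NEAT1 had a median of 0.26, with members on either side of 0, and lay above the median of all long non-coding genes by less than their SD of 0.704. A change in the transcription or decay of these RNAs in response to the material may remain as another, untested explanation, and the odds ratio was 1.54 (1.31 to 1.80) without BSG 1, M-BSG 1 and M-BSG-Hot 3.

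The deviations of BSG 1, M-BSG 1 and M-BSG-Hot 3 from the other libraries of their groups were correlated across genes, with r of 0.408, 0.278 and 0.289 for the 3 pairs and a mean of 0.325. Each had a negative slope of its deviation on gene length, -0.113, -0.102 and -0.072. With the length trend removed the mean correlation was 0.214, so the trend may account for part of the likeness but not for all of it. Without the 100 most abundant genes the mean correlation was 0.323. Every gene weighs the same in this correlation, so leaving out 100 of them could hardly change it. It therefore cannot tell whether a few genes taking most of the counts gave the likeness. NC 1 leaned the same way, less strongly: its deviation had correlations of 0.174, 0.183 and 0.124 with those of BSG 1, M-BSG 1 and M-BSG-Hot 3, its slope on gene length was -0.041, and it was kept when those 3 were left out. The labels give no batch or date, and no biological explanation was tested.

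Counted in the same way against protein-coding genes alone, long non-coding genes were also over-represented among the genes lower in M-BSG than in NC (141 of 459, odds ratio 3.78) and in M-BSG-Hot than in NC (172 of 513, odds ratio 4.38). Without BSG 1, M-BSG 1 and M-BSG-Hot 3 these odds ratios were 2.39 (191 of 881) and 3.14 (213 of 812). Among the genes lower in M-BSG-Hot than in M-BSG they were 24 of 90 (odds ratio 2.93), and 32 of 237 without BSG 1, M-BSG 1 and M-BSG-Hot 3 (odds ratio 1.26, 95% interval 0.838 to 1.85). In NC, CD68, TIE1 and SOX9, markers of immune, endothelial and other mesenchymal cells, were at 146, 236 and 236 CPM scaled by library size, and the epithelial marker EPCAM was at 15.2. The other immune, endothelial and epithelial markers were at most at 0.558 (CD14), 0.774 (PECAM1) and 0.954 (CLDN4), and among the mesenchymal ones PPARG was at 29.3, TAGLN at 12.3 and ACAN at 0.102. No hypothesis about other cells in the cultures was tested.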
